A study of Chlorocebus sabaeus with 32 samples.

How the data were processed

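Hippocampal RNA of 32 vervet monkeys (Chlorocebus sabaeus) was measured by RNA sequencing. Per the labels, total RNA was depleted of ribosomal RNA with a Ribo-Zero Gold kit before strand-preserving Illumina TruSeq libraries were made. The labels give every library the same age class, under 1 year, so all 32 form a single group. Each title carries its own identifier, and each library was therefore taken as 1 animal. Replicate numbers follow the order of deposition and only name a library. The labels give no exact age, sex or processing batch for any animal.

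The deposited table holds counts of reads per gene for the 32 libraries, with no normalization. Per the submitters' processing notes, STAR and HTSeq were used, while their versions, the genome build and the annotation are not given in the sources used here. The strand setting of the counting is not given either, so values of genes that overlap a neighbour, and of families with near-identical copies, are uncertain. The table has 33999 rows, of which 5 count reads outside genes. Those 5 were kept out of library sizes and tests. Reads in no gene feature made up 57.0% ± 3.61 (SD, n = 32) of all reads counted, reads with several alignments 8.90% ± 1.13, and reads assigned to genes 34.0% ± 2.76.

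Of 33994 gene rows, 20959 carried a symbol of the reference gene table for the assembly mChlSab1.0.hap1. A further 825 of 17250 rows named only by a gene number were given that table's symbol by matching the number. No coordinates were taken from it, because the build of the counts is not stated.

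Counts assigned to genes ran from 9347635 to 19673621 per library, with a median of 16201657. A count of 0 allows up to 3 counts, which is 0.153 to 0.321 counts relative to library size (CPM) depending on the library, and this floor covers counting error only. No pair of libraries was alike within counting noise: over the 496 pairs the chi-square per degree of freedom was at least 4.03.

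Libraries were scaled by trimmed mean of M-values (TMM) in edgeR 4.0.16 under R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, minimum total of 15 and minimum proportion of 0.7, which left 19959 genes for scores and score fits. The block comparison was filtered by block and kept 23977 genes, and the number-set comparison 21488. CPM are given as mean ± SD. Counts were tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Slopes and differences are log2 values ± standard error.

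There were 26 gene lists for cell types and processes of the maturing hippocampus, fixed before the data were examined, as were the tests, the rules for named genes and most of the alternatives. The lists hold 272 genes, of which 266 were rows of the table and 249 passed the filter. The blood list kept only 1 gene and was not scored. A list score is the mean over the list's genes of z-scored log2 CPM with a prior count of 2. Scores were compared across animals by Pearson's r and Spearman's rho with two-sided permutation tests of 100000 resamples, for which 1e-05 is the smallest possible p. Samples were to be treated as clusters if sorted scores had a gap of over 0.25 of their range with at least 3 samples on each side, and no score had one. List tests used camera with a preset correlation of 0.01 and again with an estimated correlation, and fry, in limma 3.58.1.

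The titles start with 4 digits, 2009 in 14 libraries (block A), 2010 in 16 (block B) and 2011 in 2 (block C), and go on with a number that was below 20000 in 21 libraries and higher in 11. The labels do not say what either part stands for. Libraries were compared between blocks B and A with the 2 libraries of block C in the fit, and between number sets within block B (7 low against 9 high).

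Named genes were chosen by rule. For levels these were the 12 highest mean CPM and the top 3 of each list. For variation they were the 15 largest biological coefficients of variation at a mean CPM of at least 1. For the tests they were the largest called effects at that CPM in each direction, 12 for the immature neuron score, 8 for the mature myelin score and 10 for the title comparisons. Up to 4 members with the smallest p were taken per list, and all members of both synaptic channel lists. The text gives a part of these.

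On simulated counts with 200 changed genes, the fit of the immature neuron score recovered 78% of slopes of 0.25 and 98.0% of slopes of 0.5. The block comparison recovered 78% of differences of 0.5 and 96.8% of differences of 1, and the number-set comparison 48.0% and 93.3%. Alternatives covered other scalings, other count filters, DESeq2 1.42.0, limma-trend, covariates and subsets of libraries. Some were added after the data had been seen: the share of reads in no feature and the mural and fibroblast score as covariates, presence of Y-linked counts as a covariate, leaving out each library, a filter without the block, and random lists of genes with symbols. Figures were drawn with matplotlib 3.10.9.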

Results

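Gene expression was measured in the hippocampus of 32 vervet monkeys, all labelled as under 1 year old, to examine how the transcriptome of this brain region changes in development. The labels place no animal more precisely within that age class, and no treated or control group exists. The data were therefore described as levels, as variation between animals and as covariation of gene groups across animals, and were then compared between blocks of library titles, A (14 libraries), B (16) and C (2), that share their opening digits and whose meaning the labels do not state. Library depth was 9347635 to 19673621 gene counts.

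Genes of neurons and glia were among those with the highest CPM. CPM were not divided by transcript length, so ranks between genes depend on length as well as on abundance. The highest mean CPM was that of MAP2, a dendritic microtubule protein, at 3397 ± 296 CPM (SD, n = 32). The neuropeptide-processing enzyme CPE had 3128 ± 376 CPM and the astrocytic glutamate transporter SLC1A2 2803 ± 707 CPM. The row of PARP2, named for a DNA repair enzyme, had 2709 ± 505 CPM. Its overlap with neighbouring genes was not checked, so these reads may not all come from its mRNA. The spectrin SPTBN1 had 2633 ± 203 CPM. The kinase of excitatory synapses CAMK2A reached 2154 ± 524 CPM.

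Markers of maturing and mature cells were both present. Of genes used by young neurons, STMN1 had 343 ± 117 CPM, DPYSL3 307 ± 157 CPM and NREP 171 ± 77.2 CPM (SD, n = 32). The progenitor list was led by the matrix protein TNC at 321 ± 106 CPM, and the oligodendrocyte precursor list by PTPRZ1 at 831 ± 128 CPM. Division genes had low CPM, with CENPF at 23.3 ± 5.12 CPM and PCNA at 22.4 ± 3.03 CPM. The dentate granule marker PROX1 had 122 ± 43.4 CPM, the CA pyramidal list was led by RGS14 at 141 ± 39.7 CPM, and the interneuron enzyme GAD1 had 203 ± 26.6 CPM. Hemoglobin HBB, the only blood gene past the count filter, had 3.51 ± 2.90 CPM. TTR, an abundant choroid plexus transcript, averaged 16.4 CPM with an SD of 68.0 CPM, and 4.45 CPM without replicate 22, which had 387 CPM.

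SULT1E1, CNDP1 and neurotensin varied most between animals. The estrogen sulfotransferase SULT1E1 had the largest biological coefficient of variation, 1.31, and spanned 0.172 to 71.1 CPM. CNDP1, a carnosine-splitting dipeptidase, had 1.25 with 0.388 to 38.0 CPM, and the peptide neurotensin (NTS) 1.12 with 1.51 to 128 CPM. The opioid precursor PENK reached 455 CPM in replicate 16 against a mean of 34.7 CPM, which was 21.1 CPM without that library. COL1A1, a fibrillar collagen, had a coefficient of 0.918, and the retinoic acid hydroxylase CYP26B1, listed by gene number in the table, 0.955. The median over 19959 genes was 0.148.

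Cell type lists varied more than other genes of equal expression. Of 25 lists, 20 had a median coefficient above that of random expression-matched lists at an adjusted p under 0.05, and 0 had one below. The median was 0.423 for immature neuron genes against 0.128 in random lists, 0.403 for mature myelin genes against 0.129, 0.427 for striatal and thalamic genes against 0.158 and 0.321 for immediate early genes against 0.147, each at an adjusted p of 0.0010. The 5 lists that did not pass were cell cycle, cholesterol synthesis, glucocorticoid response, early synaptic channels and inhibitory neurons. With random lists drawn from genes with a symbol 16 lists passed, and 17 by the SD of log2 CPM. Genes of a list can vary together, while random lists were drawn gene by gene, so these p-values may be too small. The smallest possible p before adjustment was 0.0002. Differences between title blocks count as variation between animals here.

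Animals with higher levels of immature neuron genes had lower levels of mature myelin genes. The immature neuron score averages genes such as DCX, SOX4 and SOX11 that young neurons express, and the myelin score genes such as MBP, MOG and OPALIN. Over 32 animals Pearson's r was -0.52 (permutation p = 0.00221) and Spearman's rho -0.44 (p = 0.0119), and r was -0.41 without the 2 animals farthest from the median. Within block B r was -0.67 (permutation p = 0.00526, n = 16). Within block A it was -0.0011 (p = 0.997, n = 14), so the relation did not hold there, and whether the blocks differ in it was not tested.

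**Figure D1:**
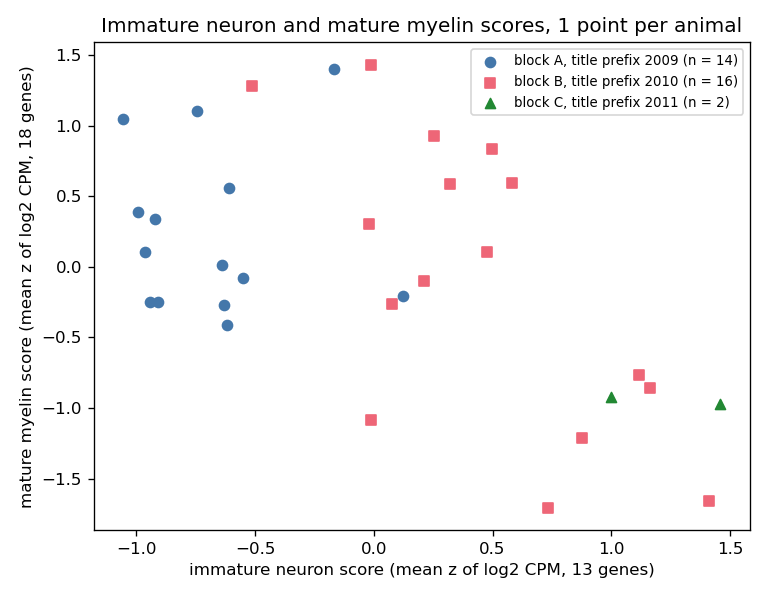
Mature myelin score (y axis) against immature neuron score (x axis), both in mean z-score units of log2 CPM, with 1 point per animal and colours for the title block. The pooled r of -0.52 comes with the 14 animals of block A mostly at the left and the 2 of block C at the lower right.

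Progenitor and glial precursor genes went with the immature neuron score, and genes of mature synapses went against it. Of the 24 other lists, 11 were positively and 7 negatively related to the score by Pearson's r, and 6 did not pass. The closest was the oligodendrocyte precursor list with r = 0.78 (rho 0.75, adjusted permutation p = 6e-05). Radial glia and progenitor genes had r = 0.76, perineuronal matrix genes 0.73 and mural and fibroblast genes 0.71, all at that adjusted p, with rho of 0.72, 0.73 and 0.76. Cell cycle genes had r = 0.67 and imprinted and fetal growth genes 0.66. CA pyramidal (0.51), newly formed oligodendrocyte (0.48), endothelial (0.46), striatal and thalamic (0.43) and cholesterol synthesis (0.39) genes were the other positive lists.

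Late synaptic channel genes, a list of channel, receptor and fast-spiking neuron genes of mature circuits, had r = -0.69 (rho -0.69, adjusted p = 0.00012). Heat shock genes had r = -0.66, immediate early genes -0.59, excitatory neuron genes -0.50, microglial genes -0.42 and astrocyte genes -0.40. Without the 2 animals farthest from the median score, 16 lists passed, and r stayed between 0.32 and 0.76 in size. Fewer lists passed within blocks, which hold fewer animals, and r shrank there in some lists but not in others. Late synaptic channel genes had r = -0.25 in block A and -0.49 in block B, and radial glia and progenitor genes 0.60 and 0.44. Perineuronal matrix genes had 0.47 and 0.60 and mural and fibroblast genes 0.73 and 0.48. None of these lists passed in either block. The immature neuron score differed between blocks A (mean -0.69) and B (0.45), so pooled r mixes differences between and within blocks. In block A only cell cycle genes passed, with r = 0.90 (adjusted p = 0.00192, n = 14). Their r in block B was 0.16 and did not pass (adjusted p = 0.694, n = 16). The lists that passed in block B were 5: oligodendrocyte precursor (0.67), imprinted and fetal growth (0.69), heat shock (-0.76), mature myelin (-0.67) and microglia (-0.66). The lists that did not pass by Pearson's r over all animals were inhibitory neuron, early synaptic channel, glucocorticoid response, interferon response, dentate granule and choroid plexus. By Spearman's rho the dentate granule (rho -0.38, adjusted p = 0.0464) and inhibitory neuron (rho 0.37, adjusted p = 0.0494) lists passed, and the astrocyte list did not (adjusted p = 0.0817).

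**Figure D2:**
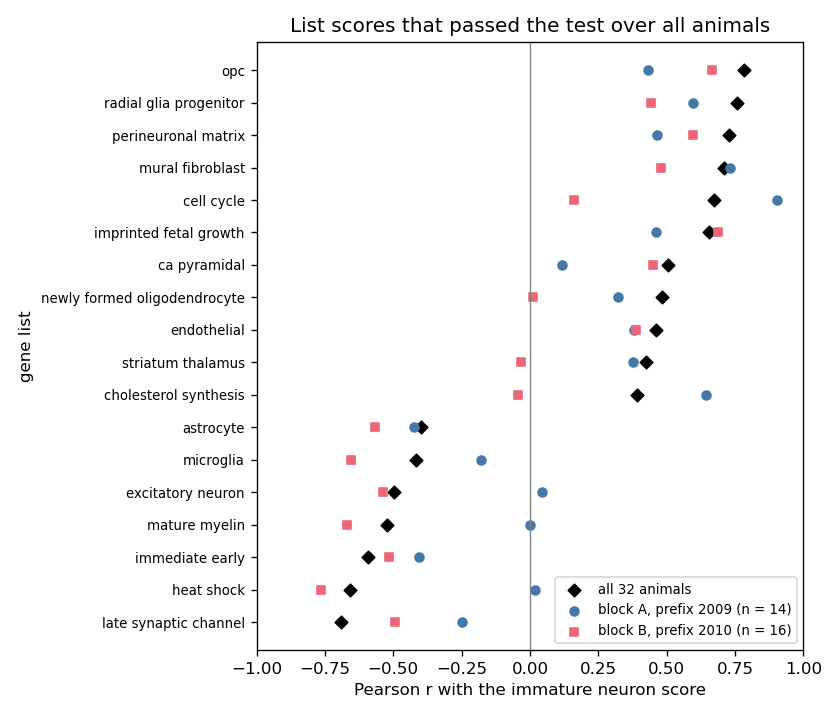
Pearson r (x axis) of each list score with the immature neuron score, for the 18 lists that passed over all 32 animals (y axis), over all animals and within blocks A and B. The oligodendrocyte precursor list lies at 0.78 and the late synaptic channel list at -0.69 over all animals.

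With the mature myelin score 2 of 24 lists passed. Immediate early genes, induced by neuronal activity, were positively related to it with r = 0.51 (rho 0.42, adjusted permutation p = 0.0335), and immature neuron genes negatively with r = -0.52. Adjusted p-values of rho were 0.161 for both. The immediate early relation was 0.30 without the 2 farthest animals, where neither list passed, so it rests on those animals. Within block A the immediate early r was -0.041 and within block B it was 0.60 (adjusted p = 0.0827). The other 22 lists did not pass, astrocyte (0.45) and microglial (0.42) genes included. The number of lists depended on the method: 8 passed (5 up and 3 down) with genes left unscaled, and 8 given the library total.

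Many of the measured genes followed the immature neuron score. Of 19946 genes outside the scoring list, 3240 were higher and 3200 lower where the score was higher, which is 32.3%. The steepest positive slopes per SD of the score were those of SULT1E1 at 1.92 ± 0.15 (SE) and neurotensin at 1.26 ± 0.22. The fibrillar collagens COL1A1 (1.07 ± 0.20), COL3A1 (0.94 ± 0.14) and COL1A2 (0.90 ± 0.14) came next. DRAXIN, an axon guidance protein, had a slope of 0.89 ± 0.07, the S-phase epigenetic regulator UHRF1 0.80 ± 0.05 and the growth factor binding protein IGFBP3 0.77 ± 0.09. The steepest negative slopes were CNDP1 at -2.26 ± 0.13 and TMEM235 at -1.22 ± 0.10. Others were ANLN (-1.03 ± 0.11), S1PR5 (-0.82 ± 0.10) and the mature myelin list members HAPLN2 (-0.88 ± 0.06) and KLK6 (-0.81 ± 0.10). By edgeR's quasi-likelihood test the adjusted p of these genes was at most 0.000106.

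Members of the scoring list itself rose with the score by construction, 12 of 13 passing, with DPYSL3 at 0.69 ± 0.04 and NEUROD1, a granule cell differentiation factor, at 0.07 ± 0.11. Oligodendrocyte precursor genes were higher in 7 of 9 members (9 when adjusted over the list alone), with OLIG2 at 0.30 ± 0.04 and PDGFRA at 0.28 ± 0.05. Perineuronal matrix genes were higher in 4 of 7 (5 higher and 1 lower adjusted over the list alone), with the link protein HAPLN1 at 0.50 ± 0.03 and ACAN at 0.41 ± 0.06. Radial glia and progenitor genes were higher in 5 of 8 (5 adjusted over the list alone), with FABP7 at 0.59 ± 0.04 and TNC at 0.41 ± 0.04. These 3 lists passed camera with a preset correlation, and each had an adjusted p = 0.212 with an estimated correlation.

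Newly formed oligodendrocyte genes were higher in 4 of 9 (4 adjusted over the list alone), with ENPP6 at 0.40 ± 0.06 and GPR17 at 0.37 ± 0.06. Cell cycle genes were higher in 9 and lower in 1 of 16 (11 and 1 adjusted over the list alone), with TOP2A at 0.31 ± 0.07. Mural and fibroblast genes were higher in 6 of 8 (7 adjusted over the list alone), imprinted and fetal growth genes in 4 of 10 with 1 lower (4 and 1 adjusted over the list alone), cholesterol synthesis genes in 8 of 16 (10 adjusted over the list alone) and endothelial genes in 5 of 10 (5 adjusted over the list alone). All 6 passed camera with the preset correlation. With an estimated correlation their adjusted p-values were 0.412 for newly formed oligodendrocyte, 0.217 for cell cycle, mural and imprinted, 0.482 for cholesterol and 0.448 for endothelial genes.

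Late synaptic channel genes were lower in 9 of 14 members and higher in 0 (11 lower adjusted over the list alone). The fast potassium channel KCNC1 had a slope of -0.37 ± 0.05, KCNA2 -0.22 ± 0.03, the neurofilament NEFH -0.25 ± 0.05, the chloride exporter SLC12A5 -0.11 ± 0.03 and the NMDA receptor subunit GRIN2A -0.15 ± 0.04. GABRD (-0.20 ± 0.05), SCN8A (-0.13 ± 0.04), SYT2 (-0.19 ± 0.06) and PVALB (-0.30 ± 0.10) also passed. KCNA1 and SCN1A were among the members that did not. Of 7 early synaptic channel genes GRIN3A (0.30 ± 0.06) and SCN3A (0.19 ± 0.03) were higher and GABRA2 (-0.13 ± 0.04) was lower, with 2 and 2 adjusted over the list alone. Without replicate 29 GABRA2 had -0.10 and an adjusted p of 0.0675. GRIN2B, GABRA3, GABRA5 and SLC12A2 did not pass.

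Mature myelin genes were lower in 10 of 18 (10 adjusted over the list alone), among them ASPA at -0.55 ± 0.08 and MBP at -0.39 ± 0.10. Heat shock genes were lower in 6 of 8 (6 adjusted over the list alone), with HSPA1A at -0.37 ± 0.05. Immediate early genes were lower in 7 of 12 (8 adjusted over the list alone), with ARC at -0.37 ± 0.08. The myelin, heat shock, immediate early and late synaptic lists passed camera with the preset correlation, with an adjusted p of 0.364, 0.217, 0.288 and 0.217 with an estimated correlation. No list kept its camera call with an estimated correlation, while 18 of 24 passed fry.

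A count of this size was not special to immature neuron genes. By limma-trend 6432 genes followed the score, while random expression-matched lists of 13 genes gave a median of 4816 and as many genes in 24 of 100 lists. With the title block as a factor 1697 genes were called, and 3287 with the mural and fibroblast score as a covariate.

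ANLN, CLCA2 and S1PR5 had the steepest positive slopes with the mature myelin score outside its own genes. Of 19941 genes outside the scoring list, 789 were higher and 701 lower where the score was higher. These slopes were ANLN at 0.94 ± 0.14, CLCA2 at 0.85 ± 0.16, S1PR5 at 0.79 ± 0.11, and the photopigment OPN4 had 0.74 ± 0.06. The steepest negative slopes of genes with a name were SULT1E1 at -1.15 ± 0.22, the cartilage protein CILP at -0.89 ± 0.24, DRAXIN at -0.66 ± 0.12, CHODL at -0.60 ± 0.18, IGFBP3 at -0.55 ± 0.11 and elastin (ELN) at -0.52 ± 0.12. By edgeR's quasi-likelihood test their adjusted p was at most 0.0339.

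Of the lists, immature neuron genes were lower in 5 of 13 members (9 adjusted over the list alone), with NREP at -0.40 ± 0.08, and radial glia and progenitor genes in 3 of 8 (3 adjusted over the list alone). Immediate early genes were higher in 3 of 12 (6 adjusted over the list alone), with ARC at 0.41 ± 0.07. Microglial genes were higher in 5 and lower in 1 of 12, with 7 and 3 adjusted over the list alone. Camera called 5 lists up and 3 down with the preset correlation and 0 with an estimated one, where the adjusted p of each of these 4 lists was 0.544. Its other calls were astrocyte, heat shock and late synaptic channel genes up and mural and fibroblast genes down. The mural and fibroblast list had a camera adjusted p = 0.0429, and 0.624 with an estimated correlation. Of its 8 members 1 was higher and 0 lower (1 and 5 adjusted over the list alone). Of genes tested with both scores 1187 were called in both, 1186 of them with opposite signs, against 479 for independent calls. The 2 scores are themselves correlated.

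Random expression-matched lists of 18 genes gave at least the 1436 genes found by limma-trend in 78 of 100 cases. The near balance of directions did not hold with fewer calls: 481 genes were higher and 188 lower with the title block as a factor, 436 and 157 without the 2 animals farthest in score, and 340 and 42 with the immature neuron score as a covariate.

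Libraries of block B had higher levels of immature neuron and glial precursor genes than those of block A. In the 16 libraries of block B, 1705 of 23977 genes were higher and 1282 were lower than in the 14 of block A. SULT1E1 rose by 3.02 ± 0.58 (log2 ± SE), from 1.25 ± 1.26 to 10.02 ± 17.1 CPM (SD), and lay above the median of block A in 16 of 16 libraries. Without replicate 29 its block B mean was 5.95 CPM. Neurotensin rose by 2.47 ± 0.49 and the thyroid hormone deiodinase DIO3 by 1.38 ± 0.27. CHODL rose by 1.37 ± 0.37 and DRAXIN by 1.29 ± 0.26. CNDP1 changed by -2.45 ± 0.47, from 24.9 ± 10.4 to 4.52 ± 7.82 CPM, and was lower in 15 of 16 libraries, with a block B mean of 2.65 CPM without replicate 30. SLC4A11 (-1.35 ± 0.28), TMEM235 (-1.33 ± 0.29), SLC5A11 (-1.21 ± 0.23) and the nodal link protein HAPLN2 (-1.17 ± 0.21) also fell. By edgeR's quasi-likelihood test the adjusted p of these genes was at most 0.0135.

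PENK (1.79 ± 0.51) and FREM3 (2.71 ± 0.83) passed too, but without replicate 16 their log2 differences were 0.79 and 1.25 and their adjusted p 0.108 and 0.205. FREM3 also missed the threshold without replicate 22 (adjusted p = 0.0566), as did ARHGAP36 without replicate 15 (0.0584).

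**Figure D3:**
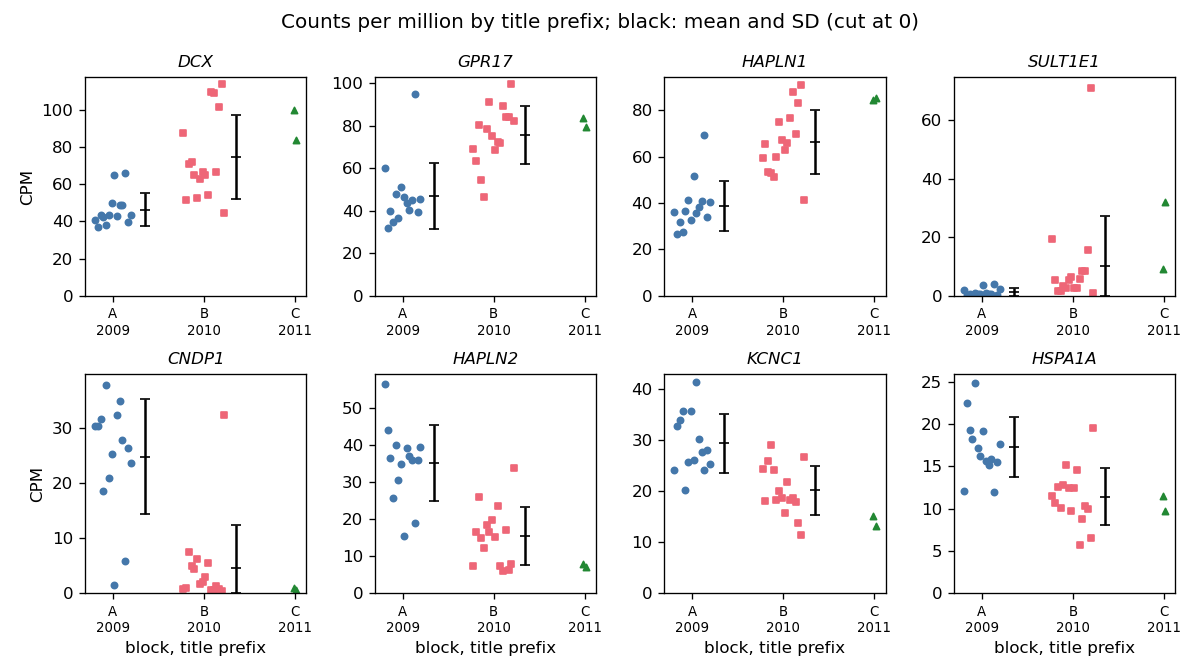
CPM (y axes) of 8 genes by title block (x axes), with 1 point per library, and black bars for the mean and SD of blocks A (n = 14) and B (n = 16), cut at 0. CNDP1 has a mean of 24.9 CPM in block A and 4.52 CPM in block B, and SULT1E1 1.25 and 10.02 CPM, of which the block B means were 2.65 CPM without replicate 30 and 5.95 CPM without replicate 29.

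Immature neuron genes rose in 12 of 13 members (12 adjusted over the list alone). SOX11 rose by 0.97 ± 0.15, from 37.9 ± 12.1 to 74.0 ± 21.4 CPM, and DCX, a microtubule protein of migrating neurons, by 0.69 ± 0.12, from 46.4 ± 8.90 to 74.6 ± 22.6 CPM. NEUROD1 differed by -0.05 ± 0.23 and did not pass. This list passed camera with the preset and with the estimated correlation (adjusted p = 0.0312). Oligodendrocyte precursor genes rose in 6 of 9 (9 adjusted over the list alone), with PDGFRA up by 0.49 ± 0.10. Perineuronal matrix genes rose in 4 of 7 (5 adjusted over the list alone), with BCAN up by 0.51 ± 0.07 and HAPLN1 by 0.78 ± 0.11. Each had an adjusted p = 0.102 with an estimated correlation. Newly formed oligodendrocyte genes rose in 5 of 9 (5 adjusted over the list alone), with GPR17 up by 0.70 ± 0.12, and radial glia and progenitor genes in 3 of 9 (4 adjusted over the list alone), with TNC up by 0.67 ± 0.11. Their adjusted p was 0.222 and 0.202 with an estimated correlation.

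Late synaptic channel genes fell in 3 of 14 (7 adjusted over the list alone): KCNC1 by -0.54 ± 0.11, KCNA2 by -0.33 ± 0.07 and SCN8A by -0.24 ± 0.07. SCN8A had an adjusted p of 0.0602 without replicate 2 and 0.0535 without replicate 4. Heat shock genes fell in 3 of 8 (5 adjusted over the list alone), with HSPA1A at -0.59 ± 0.13. Mature myelin genes fell in 3 of 18 (4 adjusted over the list alone), namely HAPLN2, KLK6 and GJB1, of which GJB1 missed the threshold (adjusted p up to 0.0717) without any 1 of 25 libraries, while MBP (-0.23 ± 0.22) did not pass. Excitatory neuron genes fell in 3 of 7 (3 adjusted over the list alone), with the glutamate transporter SLC17A7 at -0.55 ± 0.14. Late synaptic, heat shock and myelin genes passed camera with the preset correlation, with an adjusted p = 0.212, 0.222 and 0.580 with an estimated correlation. Camera called 10 lists up and 4 down with the preset correlation, and with an estimated one only the immature neuron list of these 14. Among the others, cell cycle, CA pyramidal, imprinted and fetal growth, striatal and thalamic, and immediate early genes had an adjusted p = 0.225, 0.222, 0.222, 0.222 and 0.324 with an estimated correlation. Mural and fibroblast genes, markers of vessels and meninges, passed camera as higher in block B (adjusted p = 0.000587, and 0.222 with an estimated correlation) and fry (0.00619). Of the 8 members PDGFRB rose, by 0.37 ± 0.08 (2 adjusted over the list alone), and their score was higher by 0.763 (adjusted permutation p = 0.00818).

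By list scores, 11 of 25 lists were higher in block B and 3 lower in a permutation of the 30 libraries. The immature neuron score differed most, -0.69 ± 0.33 against 0.45 ± 0.52 (SD; adjusted permutation p = 0.00025). Some libraries stood apart from their block: the score was -0.51 in replicate 30 of block B, and -0.17 and 0.12 in replicates 12 and 8 of block A. CNDP1 had 32.5 CPM in replicate 30 and 5.86 and 1.51 CPM in replicates 12 and 8, and HAPLN2 33.7, 19.1 and 15.4 CPM. The myelin score did not differ past the threshold, 0.25 ± 0.58 against -0.10 ± 1.02 (adjusted p = 0.336). With the immature neuron score as a covariate 1 gene was called between the blocks, and with the mural and fibroblast score 57. Both scores also differed between the blocks, so these fits cannot separate the block from the score. Among libraries of the lower number set alone 1162 genes were called.

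Number sets within block B gave no called gene by edgeR and limma-trend, and 194 by DESeq2. Between 9 libraries with higher and 7 with lower title numbers, edgeR's quasi-likelihood test called 0 of 21488 genes, with a smallest adjusted p of 0.0717. At an unadjusted p under 0.05 there were 3023 genes. Limma-trend called 0 genes. Of those called by DESeq2, 39 were higher and 155 lower. In the camera test with the preset correlation 1 of 25 lists passed, cholesterol synthesis, which was higher with the higher numbers and had an adjusted p = 0.914 with an estimated correlation. None of its 16 members passed the test (3 when adjusted over the list alone).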

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

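The covariates for reads in no feature and for the mural and fibroblast score, the presence of Y-linked counts, leaving out each library for the gene counts, the filter without the block and the random lists of genes with symbols were chosen after seeing the data; the other alternatives were set before. Among summary values 158 alternatives kept direction and side of the threshold with counts within 1.5 times, 24 moved further and 1 became weaker. Among single genes and lists 3190 were unchanged, 496 became weaker and 31 reversed. Unchanged means the same direction and side of the threshold or, for a mean CPM, a shift smaller than its SD. The summary values include results with each library left out in turn, so these tallies hold many settings close to the main one. No paired analysis was possible because the labels pair no libraries. Depth limits genes near the floor of 3 counts, 0.153 to 0.321 CPM. The cause of the shifts below was not tested, and the subsets also hold fewer samples.

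Genes following the immature neuron score numbered 1697 with the block as a factor, where IFI44L reversed (-0.064), 2560 in the 21 libraries with lower title numbers and 3287 with the mural and fibroblast score as a covariate. Leaving out each library gave 5892 to 6875. Lists more variable than random lists numbered 16 to 20 over the alternatives.

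Genes following the mature myelin score numbered 669 with the block as a factor, 390 in the lower number set, 593 without the 2 farthest animals and 813 without block C. They numbered 2273 with reads in no feature as a covariate and 382 with the immature neuron score as a covariate, where DPYSL5 (0.0070) and FABP7 (0.032) reversed.

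Between blocks B and A, 1328 genes differed with the number set as a second factor, 1162 in the lower number set alone, 57 with the mural and fibroblast score as a covariate and 1 with the immature neuron score as a covariate. Leaving out each library gave 2237 to 3870. With the immature neuron score as a covariate the log2 difference reversed for C1QB (-0.14), CAMK2A (0.0045), CLCA2 (0.45), CNDP1 (0.41), DIO3 (-0.14), DOCK5 (0.016), DRAXIN (-0.37), FABP7 (-0.11), GJB1 (0.50), HAPLN2 (0.13), HSPA1B (0.067), IGF2BP3 (-0.18), KLK6 (0.45), LAPTM5 (0.056), LHX6 (-0.024), LRRC53 (0.34), NPBWR1 (-0.47), PDGFRB (-0.00185), SLC5A11 (0.11), SULT1E1 (-0.56), TFAP2C (-0.022), TMEM235 (0.44) and TPX2 (-0.037). That fit called 1 gene in all and cannot separate the block from the score, so these signs are uncertain. Between number sets DESeq2 called 194 genes, and 10 were called with the immature neuron score as a covariate.

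The correlation of the immature neuron score with the myelin score was -0.0011 within block A and -0.557 to -0.460 with each library left out. Lists related to the immature neuron score numbered 9 in the lower number set, 1 within block A and 5 within block B. Within block A, r reversed for excitatory neuron (0.044) and heat shock (0.018) genes, and within block B for cholesterol synthesis (-0.043) and striatal and thalamic (-0.032) genes. Lists related to the myelin score numbered 8 without scaling of genes, 8 given the library total, 4 given reads in no feature, 3 within block B, and 0 without the 2 farthest animals, in the lower number set and within block A, where immediate early genes had r = -0.041.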

Other observations

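Microglial genes went both ways with the immature neuron score. The complement genes C1QB (0.32 ± 0.05 log2 per SD, SE), C1QA (0.32 ± 0.07) and C1QC (0.22 ± 0.06) were higher where the score was higher, while LAPTM5 (-0.30 ± 0.05), TYROBP (-0.29 ± 0.06), CX3CR1 (-0.28 ± 0.08), CSF1R (-0.23 ± 0.04) and ITGAM (-0.15 ± 0.03) were lower. That is 3 higher and 5 lower of 12 members (3 and 6 adjusted over the list alone) by edgeR's quasi-likelihood test. Of 9 inhibitory neuron genes 3 were higher and 1 was lower, as when adjusted over the list alone, and camera did not call the list (adjusted p = 0.425). The migration factor LHX6 (0.14 ± 0.04) and the peptide NPY (0.24 ± 0.08) were higher, and PVALB, a calcium buffer of fast-spiking cells, was lower (-0.30 ± 0.10). GAD1 (0.09 ± 0.03) passed too, but had an adjusted p of up to 0.0668 without any 1 of 4 libraries.

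Excitatory neuron genes were lower in 3 of 7 (3 adjusted over the list alone), SLC17A7 (-0.31 ± 0.07), CAMK2A (-0.26 ± 0.05) and NRN1 (-0.25 ± 0.05). Astrocyte genes were higher in 2 and lower in 5 of 14 (2 and 6 adjusted over the list alone). Glucocorticoid response genes were higher in 1 of 8 (KLF9, 0.10 ± 0.03), and interferon response genes were higher in 1 and lower in 1 of 12, each unchanged in number when adjusted over the list alone. Camera called none of these lists with the preset correlation.

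The covariate tests of the immature neuron score, the test of title block order and the tests of the striatal and dentate patterns were chosen after the results were seen. The labels give no age or sex per animal. Counts of the Y-linked gene USP9Y parted the libraries into 16 with over 100 counts (at least 2329) and 16 with at most 7. These are called libraries with and without Y-linked counts, and sex was tested from them. Differences in age within the first year stay open, untested.

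The first pattern is the large set of genes that follow the immature neuron score and differ between blocks. By limma-trend 1 of 100 splits, the real one, gave as many genes between blocks B and A (3003, highest other 8). This argues against a random division of the libraries, provided they are exchangeable, which the labels do not show. With 0 genes called between the number sets all 100 splits gave as many (highest other 22), which decides nothing. For the immature neuron (6432, highest other 1851) and myelin (1436, highest other 2) scores the real assignment was also 1 of 100, but this decides nothing, since scores computed from these libraries share variation with other genes for any list: random lists gave as many genes in 24 and 78 of 100 cases. Reads in no feature, library depth and sex as covariates left 98.43%, 99.72% and 97.14% of the 6440 genes called in the same direction, which argues against each as the whole cause, while the score did not differ past the threshold between the sexes (0.0688 ± 0.853 with and -0.0688 ± 0.698 without Y-linked counts, SD, permutation p = 0.617). A different share of vessel and meningeal tissue may contribute, since 48.04% stayed called with the mural and fibroblast score as a covariate, although that score itself goes with the immature one (r = 0.71). Of 3837 genes differing between block A and all other libraries by limma-trend, 81.68% had the mean of block C beyond that of block B, but 11 of 153 library pairs gave as much (7.19%), so an order by title number cannot be told apart from the spread of single libraries.

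The second pattern is striatal genes, which hippocampus expresses at low levels. In replicate 16 (block B) DRD1 had 115 CPM against a median of 17.96 CPM in the other libraries, ADORA2A 40.1 against 3.46 CPM and PPP1R1B 253 against 47.8 CPM, and PENK, RGS9, PDE10A and SYNDIG1L were also highest there. Over all libraries the 4 genes DRD1, DRD2, PPP1R1B and ADORA2A had a mean pairwise r of 0.5745 (percentile 99.99 of random expression-matched sets), and 0.2289 (percentile 95.13) without replicate 16. Since that library is highest for all 4, neither value is a test of its source, and striatal tissue in the sample and a difference within the hippocampus both stay open.

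The third pattern is the dentate granule score, which was higher in libraries with more gene counts (r = 0.73, rho 0.56, adjusted permutation p = 0.00025 over 25 lists, r = 0.61 without the 2 farthest libraries). Other scores also rose with the total: excitatory neuron (r = 0.67), heat shock (0.61), late synaptic channel (0.56) and cholesterol synthesis (0.50). Newly formed oligodendrocyte (-0.48) and imprinted and fetal growth (-0.44) scores fell with it. Their adjusted permutation p was at most 0.0391. The immature neuron (-0.07) and mature myelin (-0.10) scores did not pass. For the dentate granule score r was 0.88 within block A (permutation p = 0.00514, n = 14, and 0.62 without 2 libraries). Within block B it was 0.55 (permutation p = 0.0341, n = 16, and 0.14 without 2, so there it rests on them). Those 2 were replicates 16 and 17, and replicate 16 had a dentate granule score of -2.22. Replicate 16 was not among the 2 left out over all libraries, so it still contributes to the r of 0.61. Thinning all libraries to 9296911 counts left r with the original total at 0.7335 and moved the scores by 0.025 of their SD. Losing counts alone thus hardly changed this score. Since the scores barely moved, r could hardly change either, so the thinning does not decide whether depth is the cause. Given reads in no feature the partial r was 0.5805, which argues against them as the whole cause but does not exclude them. Replicate 1 had the largest share of such reads (67.12%), the fewest gene counts and a dentate granule score of -3.34. No partial r was computed without that library. The score rests on 3 genes, and differences in dissection or RNA yield may be involved and were not tested.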
